A study of Mus musculus with 2 samples.

How the data were processed

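The series holds H3K4me1 ChIP-seq of forebrain tissue dissected from mouse embryos at day 12.5, in 1 group of 2 biological replicates. Chromatin immunoprecipitation followed by sequencing recovers the DNA bound to histones that carry a chosen mark, and peaks are the intervals where that DNA is enriched. Per the labels, replicate 1 pooled forebrains from 120 embryos of both sexes and has 1 technical replicate, and replicate 2 pooled 68 embryos of both sexes and has 2 technical replicates. The strain was B6NCrl. Replicates therefore differ in embryos, and no other tissue, age or condition belongs to the series.

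The deposited files are peak lists in the narrowPeak format on mm10: 1 list per replicate, 1 list called on both replicates together (the pooled list) and 1 list of replicated peaks. Per the text files deposited with each sample, the replicate lists derive from the alignments of that replicate and further files whose role is not stated, and the replicated list derives from the pooled list and both replicate lists. The peak caller, its version and the rule for a replicated peak are not given in the sources used here. For every peak the deposited lists give a signal value, whose reference is not stated, and the −log10 of a p-value and of a q-value, as the authors' peak caller wrote them. These scores were used to rank or filter peaks within a list, since they are not comparable between lists. The 1 exception is a model of the dose of chromosome X, which scales the signal value and decides nothing. The depth of each library is unknown here, and no interval that needs a read count was computed. The smallest −log10 p was 2.01 in replicate 1 and 2.05 in replicate 2.

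Intervals and sequence were combined with the GRCm38 genome, which has the mm10 coordinates, and the GENCODE M21 annotation of 21938 protein-coding genes, with 1 transcription start site (TSS) per gene at the 5' end of the gene record. Chromosomes 1 to 19, X and Y were used, which left out 1 scaffold peak of the replicated list, 1 of replicate 1, 2 of replicate 2 and 2 of the pooled list. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

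A peak counted as shared when at least 50% of its length was covered by merged peaks of the other replicate. The chance level came from 100 circular shifts of the other list along each chromosome, between its first and last sequenced base. Intervals are 95% intervals from 1000 bootstraps over chromosomes, so they cover the spread over chromosomes and not that between embryos. Peaks were placed by their midpoint: within 1 kb of a TSS of any annotated gene, else in an exon, an intron or between genes. The TSS profile is the share of protein-coding TSSs covered at each 100 bp step up to 5 kb away. Promoters were CpG-rich where the observed over expected CpG ratio within 500 bp of the TSS was at least 0.6.

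Coverage of a gene is the number of bases in replicated peaks within 50 kb of its TSS. This window can hold peaks that belong to a neighbour. The median of each of 22 gene lists was placed among 10000 random lists of the same size, matched on gene length in 5 bins and on protein-coding TSSs in the window in 3 bins, drawn with replacement and without the list's own genes. Such a percentile describes these libraries and is not a p-value. For 8 pairs of lists, the difference in mean coverage was tested with a two-sided permutation test of 100000 resamples, with Benjamini-Hochberg adjustment over the 8. These tests run across genes, which are not independent replicates. The lists named telencephalon regulators, ganglionic eminence and GABAergic neurons, cortical excitatory neurons, diencephalon with hypothalamus and eye, neural progenitors, pan-neuronal genes, patterning signals, cortical hem with choroid plexus, midbrain with hindbrain and spinal cord regulators, Hox genes, late glia, erythroid, endothelial, microglia with myeloid, mesenchyme with pericytes and meninges, cardiac and skeletal muscle, liver and endoderm, pluripotency and germline, surface epithelium, housekeeping, cell cycle and olfactory receptor genes. Ahsp, an erythroid gene, was the 1 listed symbol without a match. For the replicates, the same windows were measured with the 138252 top-ranked peaks of each list by −log10 p, as many as the replicated list holds, and the difference is replicate 1 minus replicate 2 in percentage points of the window. With 1 sample on each side there is no test of that difference, and percentiles among matched random lists describe it.

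Domains are replicated peaks joined across gaps of up to 3 kb, ranked by the bases covered. For motifs, 500 bp windows centred on replicated peaks more than 2.5 kb from any TSS were compared with windows of the same GC content in 2% bins, on the same chromosome and more than 5 kb from any pooled peak. The ratio of windows holding a consensus on either strand was set beside the ratios of up to 20 shuffled forms of that consensus. A motif was called higher or lower where the bootstrap interval left out 1 and the ratio lay outside the range of its shuffled forms.

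The gene lists, motifs, tests and the rule for named genes were fixed before the data were examined. The rule names the 20 genes with the most coverage, leaving out a gene whose TSS lies within 100 kb of a higher one, then the 3 genes with the most and the 1 with the fewest covered bases of each list, the 10 largest domains, and the 5 list genes with the largest replicate difference each way. Of the named list genes, a part is printed. The calling rule for motifs, the bounds of the shifts and the exclusion of a list's own genes from its random lists were set after the files were seen, that for motifs before its results. Other overlaps, thresholds, windows, matching, gaps and single replicates were tried as alternatives. Loci join the genes of a list whose neighbouring TSSs lie within 100 kb. Smaller top-ranked sets hold 50% as many peaks, of the shorter list for replicate overlap and of the replicated list for gene windows.

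The steps were tested on simulated data. With 60% of peaks copied from replicate 2 and the others at random positions, 61.5% were recovered as shared against 61.6% set. Of 1000 random lists of 18 genes, 5.7% lay outside percentiles 2.5 and 97.5, and with coverage tripled 87.7% lay above percentile 97.5. Of 1000 permutation tests of 15 against 20 random genes, 4.2% gave p under 0.05, after 9% in a first run of 200 tests that led to the larger number, and with 10 kb added to the 15 genes 97.4% did. A planted motif gave a ratio of 2.82, as set, and a motif not planted gave 0.993.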

Results

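H3K4me1, the monomethylated form of lysine 4 on histone H3, is known as a mark of enhancers and of the flanks of active promoters. It was mapped by ChIP-seq in the forebrain of mouse embryos at day 12.5, when the cerebral cortex and the ganglionic eminences are producing neurons. The series has 1 group of 2 biological replicates, pools of 120 and 68 embryos. The design thus gives a map of the mark in 1 tissue and 1 comparison, that of replicate 1 with replicate 2. The replicate 1 list held 185242 peaks covering 89.1 Mb (3.36% of the genome), and the replicate 2 list held 205793 peaks covering 99.4 Mb (3.76%). The pooled list held 269331 peaks and the replicated list 138253 peaks with a median width of 555 bp, covering 107.1 Mb (4.05%). Positions are given on mm10, and read depth is unknown. Values below come from the replicated list, with those of the single replicates beside some of them. Both replicates can lie on the same side of the replicated list, as for the TSS profile and the domains. Their values thus show how the replicates differ and do not measure the spread of the replicated list.

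The mark lay mostly in introns, and nearer to promoters than shifted peaks. Of replicated peaks, 54.5% had their midpoint in an intron (95% interval 53.7% to 55.4%), against 42.0% after circular shifts, and 26.5% lay between genes, against 50.02%. A further 12.9% lay within 1 kb of a TSS (12.2% to 13.6%), against 3.92% after shifts, and 6.03% lay in exons, against 4.08%. The median distance to the nearest TSS was 12.6 kb, against 21.6 kb after shifts, and 75.8% of peaks were more than 2.5 kb from any TSS, against 90.7%. With as many top-ranked peaks, the share within 1 kb of a TSS was 12.98% in replicate 1 and 13.2% in replicate 2.

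Around promoters the mark flanked the TSS and was low on it, and this shape belonged to CpG-rich promoters. Among 10083 genes with CpG-rich promoters, 13.8% of TSSs were covered, against 64.9% at 1000 bp downstream and 44.6% at 600 bp upstream. At 11855 CpG-poor promoters there was no such dip, with 19.2% covered at the TSS and a maximum of 20.0% at 500 bp downstream. A replicated peak lay within 2 kb of 95.8% of CpG-rich TSSs and of 38.9% of CpG-poor ones. Over all genes the share covered at the TSS was 0.433 of the maximum within 2 kb, and it was 0.374 in replicate 1 and 0.383 in replicate 2 with as many top-ranked peaks.

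**Figure D1:**
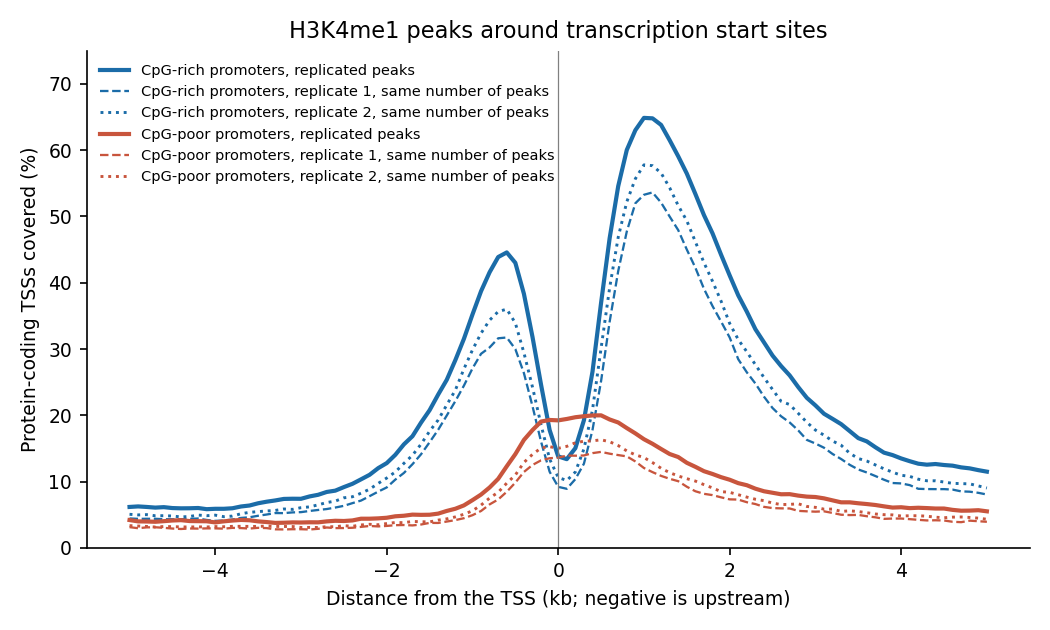
Share of protein-coding TSSs covered by H3K4me1 peaks (%) against distance from the TSS (kb), for CpG-rich and CpG-poor promoters; solid lines are replicated peaks and broken lines the top-ranked peaks of each replicate. CpG-rich promoters had 13.8% at the TSS between flanks of 44.6% and 64.9%, and CpG-poor promoters had their maximum of 20.0% at 500 bp downstream.

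Genes that pattern the forebrain carried several times more of the mark than matched genes. Across 21938 protein-coding genes the median coverage within 50 kb of the TSS was 4.68 kb, and 3854 genes (17.6%) had none. The 15 telencephalon regulators had a median of 21.7 kb, against 2.84 kb in matched random lists, and the 18 neural progenitor genes had 17.8 kb against 3.05 kb. For 20 patterning signal genes the median was 17.2 kb against 3.64 kb, and all 20 lay above the median of all genes. The 15 genes of the diencephalon, hypothalamus and eye had 12.2 kb, the 20 cortical excitatory genes 11.7 kb and the 18 ganglionic eminence and GABAergic genes 10.1 kb. Each of these 6 lists lay at percentile 99.98 or above among 10000 matched lists, and at 99.91 or above with either replicate alone.

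Nr2e1, a nuclear receptor of neural stem cells, led the telencephalon list with 30.3 kb, followed by Otx1 (25.5 kb) and Pax6 (24.3 kb), a regulator of cortical progenitors. Foxg1, the forkhead factor needed for telencephalon growth, had 5.60 kb; it was named for its role after the values were seen. Arx, on chromosome X, had the least of the list at 2.49 kb. Among progenitor genes, the receptor Notch1 (44.5 kb), the intermediate filament gene Nes (34.98 kb) and the neural stem cell factor gene Sox2 (33.3 kb) had the most, and the matrix gene Tnc had the least (2.73 kb). The signalling list was led by Ptch1, the hedgehog receptor (33.9 kb), Fgfr3 (31.9 kb) and the Wnt antagonist gene Sfrp1 (31.4 kb). In the ganglionic eminence list Bcl11b had 42.9 kb, the proneural gene Ascl1 19.7 kb and Dlx1 18.9 kb, while Isl1 had 2.30 kb. In the cortical excitatory list Bcl11a had 39.1 kb, Neurog1 28.5 kb and Neurod2 27.4 kb, while Reln had 3.38 kb. Tcf7l2, a Wnt pathway effector, led the diencephalon list with 32.3 kb.

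Lists of other regions and of later cell types were also above matched genes. The 20 midbrain, hindbrain and spinal cord regulators had a median of 9.75 kb against 2.74 kb (percentile 99.96), led by Pax7 (32.3 kb) and Lmx1b (26.6 kb). As with the patterning signals, all 20 lay above the median of all genes, and so did all 15 cell cycle genes. The 14 cortical hem and choroid plexus genes had 10.9 kb (percentile 99.96), with Wnt3a at 14.98 kb and Ttr, the choroid plexus transthyretin gene, at 2.32 kb. For 15 late glial genes the median was 11.2 kb (percentile 99.5), led by the oligodendrocyte lineage genes Olig1 (25.8 kb) and Olig2 (22.9 kb). Cell cycle genes had 10.2 kb (percentile 98.9), mesenchyme, pericyte and meninges genes 7.55 kb (98.6), housekeeping genes 9.92 kb (97.8) and pan-neuronal genes 8.46 kb (97.7). Of these, the pan-neuronal list lay at 92.6 with replicate 1 alone and 94.96 with replicate 2 alone. With replicate 1 alone the housekeeping list lay at 96.3 and the mesenchyme list at 97.4, which ended these calls. Housekeeping and cell cycle genes lay at 86.5 and 92.3 when lists were matched also on promoter CpG. Within 10 kb of the TSS late glial genes lay at 78.4 and choroid plexus genes at 94.3, and within 100 kb mesenchyme genes lay at 72.95 and cell cycle genes at 90.2.

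Lists of distant tissues lay within the range of matched genes. Percentiles were 95.9 for cardiac and skeletal muscle, 78.9 for endothelial, 53.3 for microglia and myeloid, 39.9 for liver and endoderm, 36.9 for pluripotency and germline, 32.8 for surface epithelium, 32.5 for Hox and 14.8 for erythroid genes. Single members of these lists stood out. Some of them share the window with neighbours, and whether the covered bases belong to those was not tested. Nfe2, an erythroid factor with 28.2 kb, lies beside Cbx5 and Hnrnpa1, and Klf1 with 18.1 kb lies beside Mast1 and Farsa. The haemoglobin gene Hbb-bs, the integrin gene Itgam, the collagen gene Col3a1, the liver cytochrome gene Cyp3a11 and the keratinocyte gene Ivl had 0 kb. Matched also on promoter CpG, cardiac and skeletal muscle genes lay at 98.2 and Hox genes at 0.09. The 39 Hox genes form 4 loci with shared windows, and with 1 gene per locus, a setting added after the data were seen, they lay at 14.6. The list of 1093 olfactory receptor genes lay below matched genes (percentile 0), and 908 of them (83.1%) had no covered base. These genes form 85 loci, and with 1 gene per locus they lay at 0, or at 31.02 when matched also on promoter CpG, which ended the call.

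**Figure D2:**
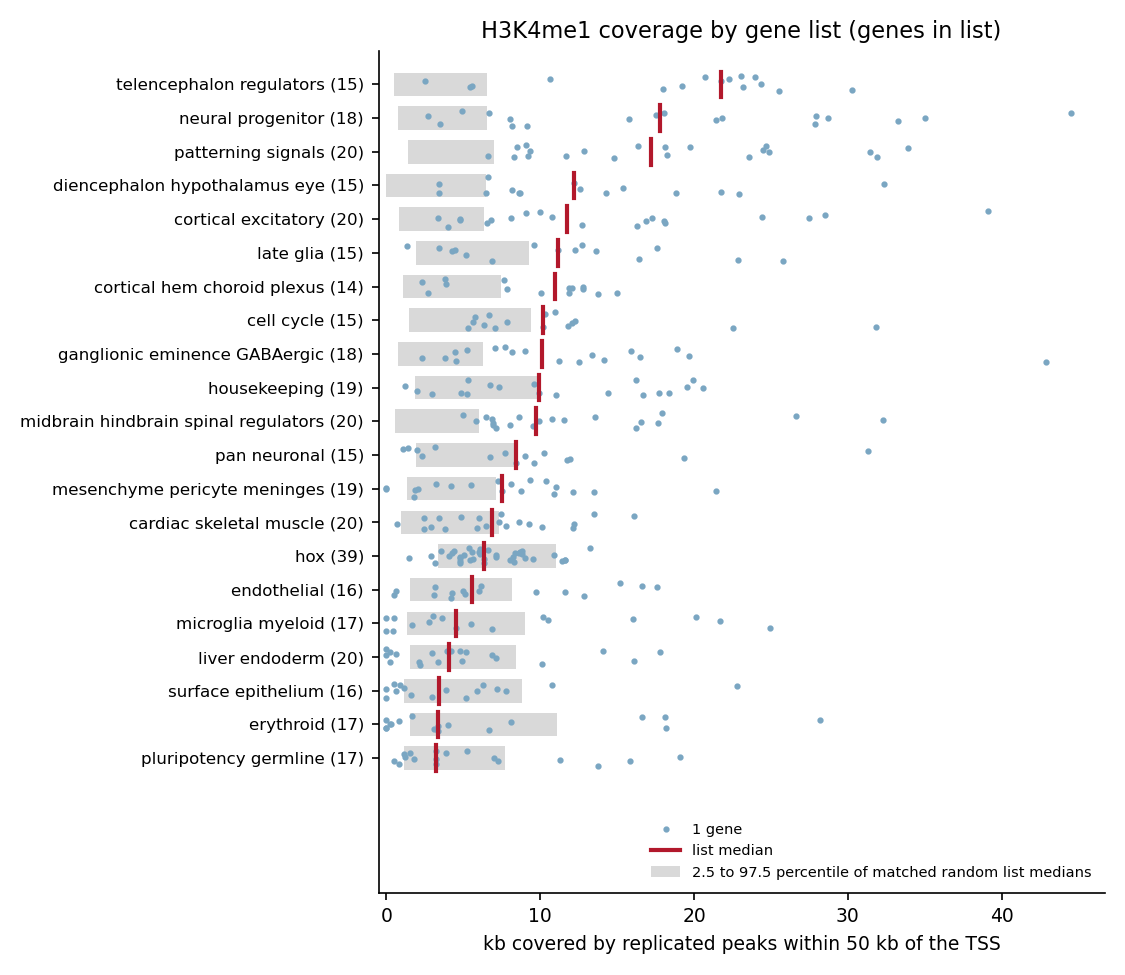
Coverage by replicated H3K4me1 peaks within 50 kb of the TSS (kb) for the genes of 21 lists, with the number of genes in brackets; points are genes, red bars list medians and grey bars the central 95% of 10000 matched random list medians. The telencephalon median of 21.7 kb lay farthest above its grey bar, and the erythroid, pluripotency and epithelium medians lay inside theirs.

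Tests of list against list separated housekeeping genes from olfactory receptor genes, and telencephalon regulators from Hox genes only where Hox genes counted singly. Telencephalon regulators had a mean of 18.4 kb ± 8.37 (SD, n = 15 genes) and Hox genes, which pattern the trunk and hindbrain, 6.85 kb ± 2.70 (n = 39 genes). The difference of 11.6 kb had p = 1e-05 in a two-sided permutation test, the smallest the permutations can give (adjusted p = 4e-05). With the 4 Hox loci in place of the 39 genes, a setting added after the data were seen, the difference was 11.6 kb (permutation p = 0.0171, adjusted p = 0.0562), which did not pass. Housekeeping genes exceeded olfactory receptor genes by 10.7 kb with an adjusted p of 4e-05 in the permutation test, and by 9.91 kb over 85 olfactory receptor loci (adjusted p = 8e-05). Telencephalon regulators exceeded midbrain, hindbrain and spinal cord regulators by 6.20 kb (permutation p = 0.0266, adjusted p = 0.0710), which did not pass. This contrast depended on the replicate: it was 6.71 kb with replicate 1 alone (permutation test, adjusted p = 0.00725) and 1.80 kb with replicate 2 alone (adjusted p = 0.720). Without genes of X and Y, an alternative added after the data were seen, it was 7.34 kb (permutation test, adjusted p = 0.0202). Neural progenitor genes exceeded late glial genes by 7.44 kb (permutation p = 0.0474, adjusted p = 0.0947), which did not pass. Within 10 kb of the TSS it was 3.86 kb and passed (permutation test, adjusted p = 0.0142). Mesenchyme genes exceeded liver genes by 1.97 kb (adjusted p = 0.419 in the permutation test), and by 1.73 kb within 10 kb, which passed (adjusted p = 0.0164). Pan-neuronal against muscle genes gave 1.89 kb (permutation test, adjusted p = 0.514), and ganglionic eminence against cortical excitatory genes −2.28 kb (adjusted p = 0.539). Endothelial against microglial genes gave −0.179 kb (permutation test, adjusted p = 0.942), with 0.792 kb over loci, 0.357 kb in replicate 1 alone and −0.860 kb in replicate 2 alone. The tests run across genes, which are not independent replicates.

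Flrt1, which codes for a leucine-rich repeat transmembrane protein, led with 63.2 kb of its window covered (chromosome 19, TSS at 7105729; 52 kb in replicate 1 and 59.4 kb in replicate 2). Ccdc85c followed with 60.6 kb, then Tcf20 with 59.1 kb and the nuclear corepressor gene Ncor2 with 56.8 kb. The ephrin gene Efna2 had 56.8 kb and the Eph receptor gene Ephb2 54.9 kb. The corepressor Tle3 had 49.9 kb, the LIM-domain cofactor gene Ssbp3 50.2 kb, the reelin receptor gene Lrp8 47.4 kb and the forkhead gene Foxp4 46.0 kb. Pipox, a gene of amino acid oxidation with 56.3 kb, shares its window with the neuronal gene Sez6. The others of the 20 were Bahcc1, G430095P16Rik, Zmiz1, Igdcc3, Fam222a, Enho, Ifrd2, Cdh22 and Cxxc5, the last with 44.9 kb.

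Joined across gaps of up to 3 kb, the replicated peaks formed 66189 domains, of which 745 had at least 10 kb covered. The largest overlapped Msi2, a neural RNA-binding protein gene, on chromosome 11 from 88389322 to 88609624, with 170 kb covered in 85 peaks (150 kb in replicate 1 and 159 kb in replicate 2). It held no protein-coding TSS, and the TSS nearest to its middle was that of Ccdc182, 205 kb from that point. The next were at Ephb2 on chromosome 4 from 136697902 to 136841255 (108 kb covered) and at Ssbp3 on the same chromosome from 106907417 to 107027359 (100.2 kb). A run of 3 domains overlapped Gse1 on chromosome 8, with 83.0, 81.8 and 64.8 kb covered. The others of the 10 largest were at Flrt1 (68.0 kb), Sema5b (60.3 kb), Tcf20 (58.4 kb) and Ccdc85c (57.5 kb). Of 3148 domains with at least 5 kb covered, 39.0% held a protein-coding TSS, against 13.7% of all domains. With 1 replicate alone the count with at least 10 kb covered was 409 or 470, and the largest domain lay at Gse1 (90.6 kb, replicate 1) or Ssbp3 (91.1 kb, replicate 2). Size and place of the largest domain also depended on the gap: 75.2 kb on chromosome 8 with 1 kb and 306 kb on chromosome 11 with 12.5 kb. At −log10 q of 5 or more it had 88.9 kb covered on chromosome 11.

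Distal peaks held homeodomain, SOX, MEIS/TGIF and MEF2 motifs more often than background in every setting run, while the call for CTCF motifs held in part of them. Among 104808 distal peaks with 89865 matched windows, the homeodomain core TAATTA occurred in 16.8% of peak windows and 9.04% of background windows, a ratio of 1.86 (95% interval 1.79 to 1.93), above the 1.36 of its highest shuffled form. The E-box CAGCTG had a ratio of 1.37, the TCF/LEF consensus 1.33, the SOX consensus 1.32, the POU octamer 1.43, the MEIS/TGIF consensus 1.20 and the TEAD consensus 1.19, each above all its shuffled forms. The MEF2 consensus had a ratio of 2.20 (2.02 to 2.38) and the CTCF consensus 2.20 (1.80 to 2.66). The full NFI palindrome was in 17 peak windows and 1 background window, with 1 usable shuffled form, too few to read. With it 10 of 18 motifs were called higher, without it 9, and 0 were called lower. The E-box CAGATG (1.01), GATA (0.986), AP1 (1.097), RFX (1.399) and the NFI site with a single arm (1.11) lay within the range of their shuffled forms, as did the PU.1/ETS (0.881) and HNF4 (1.24) consensus. The NRF1 interval, 0.815 to 2.14, included 1, while with replicate 1 alone NRF1 was called higher (1.67), with 1 usable shuffled form. Repeat sequence made up 13.6% of peak windows and 40.9% of background windows. With replicate 1 alone the calls for POU (1.36), CAGCTG (1.34) and NFI (8) ended, and with replicate 2 alone that for NFI (9). The SOX call held by a small margin with 1 replicate alone. Its ratio was 1.306 against 1.294 for its highest shuffled form in replicate 1, and 1.272 against 1.271 in replicate 2. In 1000 bp windows POU (1.25) and CAGCTG (1.26) lost their calls, and in 200 bp windows RFX (1.52) gained one, as it did in 3 settings added after the data were seen. The CTCF motif lost its call in 200 bp windows (ratio 1.18), with replicate 1 alone (2.07), with flanking background (1.71) and with peaks touching both replicates (1.93), the last pair of settings added after the data were seen. With repeats masked, also added later, ratios were higher for shuffled forms as well, since more of the background is repeat. The homeodomain ratio was 2.80 (2.08 for its highest shuffled form) and the POU ratio 2.99 (highest shuffled form 1.90), and TEAD (1.52) and TCF/LEF (1.77) lost their calls.

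Replicate 1 was then compared with replicate 2. Of replicate 1 peaks, 59.8% had at least 50% of their length covered by replicate 2 (95% interval 59.0% to 60.5%), against 4.01% after shifts. Of replicate 2 peaks, 50.6% were covered by replicate 1 (49.9% to 51.3%), against 3.58%. The bases covered in both made up 0.481 of the bases covered in either, against 0.0204 after shifts. Overlap was higher for stronger peaks, from 35.97% in the weakest decile of the replicate 1 list to 96.7% in the strongest, and from 24.7% to 95.2% in the replicate 2 list. Coverage per gene had a Spearman correlation of 0.977 between replicates, across genes, which are not independent replicates.

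**Figure D3:**
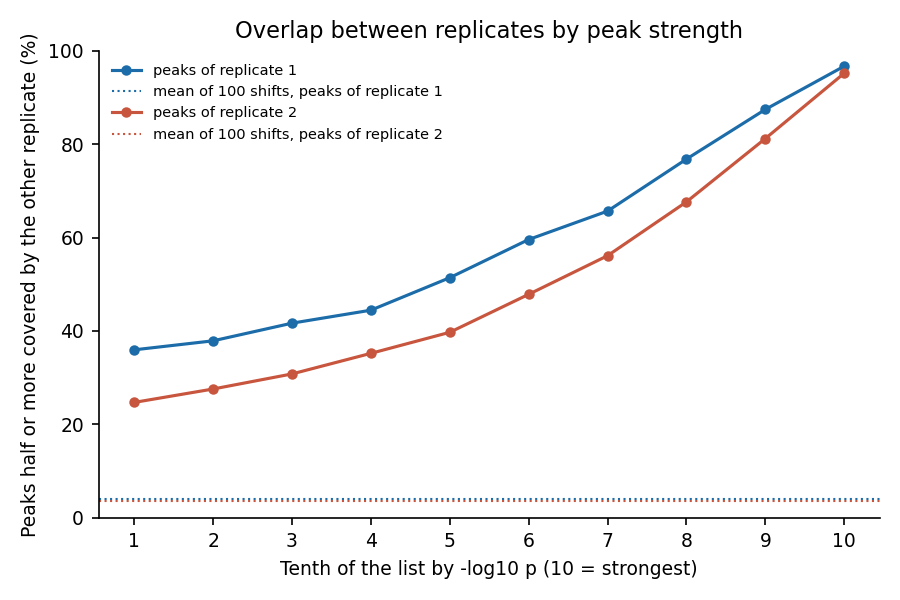
Share of peaks with at least 50% of their length covered by the other replicate (%), by decile of the list ranked on the authors' −log10 p, with dotted lines for the mean of 100 circular shifts. The strongest decile had 96.7% for replicate 1 and 95.2% for replicate 2, against 4.01% and 3.58% after shifts.

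The replicated list held 51.3% of pooled peaks and 78.7% of their bases, with the pooled interval kept in each case. Of its peaks, 77.5% touched a peak in both replicate lists, and 59.4% had at least 50% of their length covered by both. The remaining 31071 (22.5%) did not touch both: 11596 touched only replicate 1, 17729 only replicate 2 and 1746 neither.

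The replicates differed in the regional identity of the marked genes. Midbrain, hindbrain and spinal cord regulators had more of the mark in replicate 2: the median difference was −2.57 percentage points of the window, with 17 of 20 genes higher in replicate 2 (percentile 0 among matched lists). Telencephalon regulators had more in replicate 1, by a median of 0.951 points, with 10 of 15 genes higher there (percentile 100). The list genes farthest toward replicate 2 were Pax7 (18.2% of the window in replicate 1 and 36.9% in replicate 2), Pax3 (9.06% and 21.6%) and En2 (6.46% and 18.8%), all regulators of dorsal neural tube or midbrain. The complement genes C1qb and C1qa, whose windows overlap, came next (15.2% and 24.9% for C1qb). Both windows also overlap that of Ephb2, which had 40.7 kb covered in replicate 1 and 51.5 kb in replicate 2. Farthest toward replicate 1 were the cortical regulator Emx1 (20.8% and 12.01%), Bcl11a (31.5% and 24.2%), Gsx2 (14.6% and 7.30%), Fezf2 (18% and 10.8%) and Dlx1 (18.5% and 11.5%), genes of the cortex and ganglionic eminence. The ganglionic eminence list as a whole had 7 genes higher in replicate 1 and 11 in replicate 2, and the cortical excitatory list 10 and 10. Over all genes the difference had a median of −0.213 points, with 95% between −3.77 and 1.91. Unrelated lists also counted toward replicate 2: 17 of 20 liver and endoderm genes, 15 of 17 microglial and 14 of 19 housekeeping genes. Progenitor (11 of 18) and patterning (12 of 20) genes counted toward replicate 1. The count for midbrain, hindbrain and spinal cord regulators is thus not particular to them, while their median lay farthest toward replicate 2.

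Cardiac and skeletal muscle genes (−1.38 points, percentile 0.03), Hox genes, which share windows (−1.12, percentile 0.17), cortical hem and choroid plexus genes (−1.09, percentile 0.475) and cell cycle genes (−1.06, percentile 2.11) lay toward replicate 2. Patterning signals (0.260 points), neural progenitor genes (0.195) and cortical excitatory genes (0.0435, with 10 of 20 genes each way) had positive medians, at percentiles above 99. The upper ends of their matched ranges were 0.0075, 0.01 and 0 points, so nearly any positive median would pass. These percentiles therefore do not establish a lean to replicate 1. For telencephalon regulators that end was 0 points too, beside their median of 0.951 points. Their mean was 1.07 points ± 4.76 (SD, n = 15 genes), with 5 of 15 genes higher in replicate 2. Their percentile of 100 thus does not measure the size of the lean. In the olfactory receptor list 45 of 1093 genes were higher in replicate 1 and 172 in replicate 2. Most of its genes had no peak, which fixes its median at 0, so its percentile of 100 decides nothing. The other 12 lists lay within the central 95% of matched lists: pan-neuronal 6.46, ganglionic eminence 23.7, diencephalon 19.9, late glia 32.3, erythroid 87.4, endothelial 19.6, microglia 12.2, mesenchyme 28.2, liver 2.56, pluripotency 20.0, epithelium 29.4 and housekeeping 12.4. The cortical excitatory list turned to percentile 37.5 with all peaks and to 0 with the smaller top-ranked set. With that set progenitor genes went to 24.6, muscle genes to 47.6, Hox genes to 5.47, choroid plexus genes to 3.87 and cell cycle genes to 6.17, and patterning signals went to 77.98 with all peaks. The telencephalon and midbrain lists stayed at 99.93 or above and at 0 in every setting run. Percentiles at the ends of their scale do not show how far the difference in points moved. The Hox list went to 62.5 with list means, a setting added after the data were seen. With 1 sample on each side, these differences compare 2 libraries and have no replicate check.

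**Figure D4:**
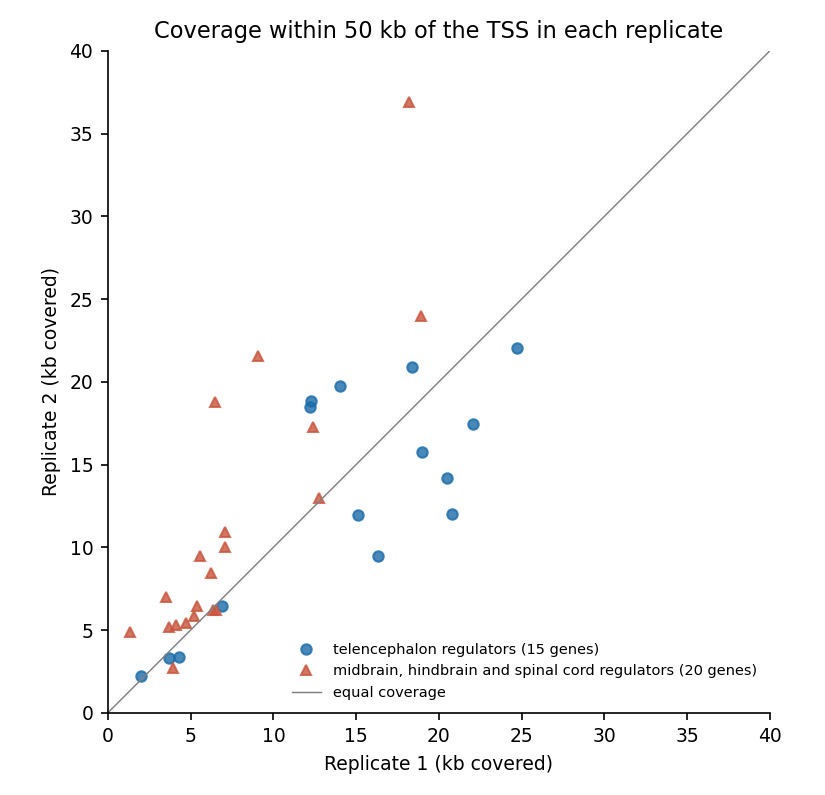
Coverage within 50 kb of the TSS (kb) in replicate 2 against replicate 1, with as many top-ranked peaks from each, for telencephalon regulators (circles, 15 genes) and midbrain, hindbrain and spinal cord regulators (triangles, 20 genes); the line marks equal coverage. Of the triangles 17 lie above the line, and of the circles 10 lie below it.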

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

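Settings that added peaks touching both replicates, autosomal genes, loci, other matching for the replicate difference, list means, flanking background or masked repeats were tests chosen after the data were seen; the others were fixed before. Comparisons between replicates cannot be made with a replicate left out. The contrast of housekeeping with olfactory receptor genes passed under every setting run for it. Matching on promoter CpG was not run for pairs of lists, and 14 of 19 housekeeping but 0 of 1093 olfactory receptor genes were CpG-rich. The contrast of telencephalon regulators with Hox genes passed under all settings but the mean of each locus (11.6 kb, permutation test, adjusted p = 0.0562), where 4 loci replace 39 genes. Replicate overlap moved with its definition: for replicate 1 and 2 peaks it was 70.1% and 61.4% at 1 bp, 42.1% and 32.1% at 80% of the peak, and 61.9% and 57.3% with the smaller top-ranked set. Merging within 1 kb gave 60.6% for replicate 1, and −log10 q of 2 or more gave 52.9% for replicate 2. The share of bases in both was 0.488 at that q, 0.5002 with the smaller set and 0.541 after merging. The pooled peaks touching both replicates at 1 bp were 40.2%, and at −log10 q of 2 or more 60.3% of pooled peaks were kept. Peaks within 1 kb of a TSS were 12.98% to 13.2% with 1 replicate alone, 15% at −log10 q of 5 or more, 14.4% with peaks touching both replicates and 9.49% with protein-coding genes only; 24.2% lay within 2.5 kb. The TSS ratio was 0.374 to 0.383 with 1 replicate alone, 0.401 at −log10 q of 5 or more, 0.417 with peaks touching both and 0.455 over every transcript start.

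Between 10 and 13 gene lists lay above their matched range. Matching on promoter CpG put 2 lists below it, with Hox at 0.09 (14.6 with 1 gene per locus, where 0 lists lay below and olfactory receptor genes lay at 31.02), and took housekeeping to 86.5 and cell cycle to 92.3. The telencephalon contrast with midbrain, hindbrain and spinal cord was 1.80 to 6.71 kb with 1 replicate alone and 7.34 kb with autosomal genes. Within 10 kb of the TSS, progenitor against late glial genes (3.86 kb, permutation test, adjusted p = 0.0142) and mesenchyme against liver genes (1.73 kb, adjusted p = 0.0164) passed; the cause was not tested. For the replicate difference, 3 lists lay above with all peaks, 3 above and 3 below with the smaller set, and 3 below with list means. The main setting had 5 above and 5 below. Those above included the void olfactory receptor list and the patterning, progenitor and cortical excitatory lists, whose matched ranges ended near 0. The reversed lists were cortical excitatory (37.5 with all peaks, 0 with the smaller set), progenitor (24.6 with the smaller set) and Hox (62.5 with means); the cause was not tested. Domains were 35276 with a 12.5 kb gap, as more peaks join. Those with at least 10 kb covered were 409 to 470 with 1 replicate alone, 335 with a 1 kb gap and 1932 with a 12.5 kb gap. The pan-neuronal list gained a replicate difference with all peaks (0.68), and the ganglionic eminence (99.2) and microglial (0.05) lists with means. Between 7 and 10 motifs were higher, and 0 lower in each setting. Depth is unknown, so a missing peak is not shown to be a missing mark.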

Other observations

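The gene families and all tests except that of repeats and that of the second regulator lists were chosen after the result was seen, and the genes of the second lists were picked once the pattern had been seen but before their values were. Gene families, grouped by the letters before the first digit of their symbol, gave a wider view of where the mark lay. Of 269 families with at least 10 genes, those with the highest medians included Arid genes, named for a DNA-binding domain (17.3 kb, against 4.65 kb in matched lists), Srsf splicing factors (15.8 kb), Tcf factors (14.9 kb), Sema guidance cues (14.04 kb), Wnt ligands (12.9 kb), Sox factors (12.4 kb) and Fzd receptors (11.7 kb), each at percentile 99.94 or above. They are examples: with clustered genes counted singly, 17 families lay above and 29 below matched genes at a cut-off of 0.05. The cut-off applied to a value derived from each family's percentile among matched random lists and adjusted over the 269 families. Such a percentile is not a p-value, so the counts describe these libraries and are not tests. Chd (13.1 kb), Ndufb (12.1 kb) and Hdac (11.99 kb) genes did not reach the cut-off. The Rps (9.56 kb) and Rpl (8.60 kb) families were also high. They hold ribosomal protein genes, but grouping by symbol can take in other genes with the same letters. At the other end, the vomeronasal receptor family Vmn (331 genes), the Defb defensins (42) and the Serpina genes (24) had medians of 0 kb. The Cyp genes (100) had 0.432 kb and the Krtap keratin-associated genes (57) 0.296 kb. The clustered protocadherins, which code for neuronal adhesion proteins, were low too, with 0 kb for Pcdha and Pcdhb and 0.450 kb for Pcdhga. Members of such clusters share windows, so each of these 3 groups is 1 locus.

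Replicate 2 had more of the mark around midbrain, hindbrain and spinal cord regulators and replicate 1 around telencephalon regulators. Matched on mean coverage, the midbrain list stayed at percentile 0 and the telencephalon list at 99.98 or above. A difference in enrichment or calling threshold that moves genes by their coverage thus does not account for this pattern. Peak strength was not matched, so a difference that acts on weak peaks stays open. After matching on promoter CpG the percentiles were 0 and at least 99.99, which argues against a bias tied to CpG within 500 bp of the TSS. GC content in the rest of the window was not matched, so a GC bias there stays open. In a second pair of lists, 15 telencephalon genes averaged 1.41 points and 20 midbrain and hindbrain genes −2.40 (permutation p = 1.00e-05, the smallest the permutations can give), with 12 of 15 higher in replicate 1 and 19 of 20 in replicate 2; this test runs across genes and describes 1 library per side. Different shares of midbrain or hindbrain tissue in the pools may contribute, but the second lists hold relatives of genes already seen, and genes also active in the diencephalon. Genes in general leaned to replicate 2 (median −0.213 points), so a count of genes higher there is not by itself regional. Muscle genes leaned beyond their matched range (percentile 0.03, but 47.6 with the smaller top-ranked set), and a difference in embryo stage was not tested.

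Of the replicated peaks, 31071 did not touch a peak in both replicate lists, which excludes a rule that each replicated peak overlaps both lists as deposited. They were weak: 96.8% had a pooled −log10 p under the median of the peaks touching both, with a median of 6.28 against 10.9. They may be peaks that fell under the cut-off of a deposited replicate list; which lists the authors compared stays open.

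Chromosome X held far less of the mark than any autosome, with 0.430% covered against 3.23% on chromosome 3, the lowest autosome, and it was low in each replicate too (0.310% and 0.387%). Gene content does not account for it, since the 948 X genes had a median of 0 kb against 3.88 kb in matched autosomal lists (percentile 0). Repeats marked in the genome sequence do not either. Outside them the share on X was 0.166 of that on chromosome 16, the lowest autosome by that measure. Poor mapping outside marked repeats was not tested. X had 0.190 of the autosomal peaks per gene. A lower dose of X could leave fewer peaks over a threshold: modelled at the fifth percentile of signal, the X share was 1.19 times that left by a halved dose and 0.314 times that left by a dose of 0.75. Pools with equal shares of both sexes have a dose of 0.75, and the labels give embryos of both sexes in each pool. The halved dose, whose value lay nearer, is thus not the dose of such pools. Since the threshold and the scaling of signal with dose are assumed, neither value decides, and dose, X inactivation and lower H3K4me1 on X all stay open.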
